A study of Mus musculus with 6 samples.

How the data were processed

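Total RNA of 6 mouse tumor samples was measured with a NanoString nCounter panel, per the labels' protocols, which state that no dye label was used. The tumors had grown in the liver from cells of a BALB/c liver cancer line carrying either a PD-L1 plasmid or the empty plasmid, with 3 samples in each group. Samples were grouped by their titles, which also give replicate numbers 1 to 3.

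The deposited values are on the log2 scale and had been scaled per sample by the authors, by a factor whose basis is not given in the sources used here. This was read from the values: in every sample, 2 to the power of the value equalled a whole number times a factor plus a constant of 0.158 that all samples share. All values came out whole within a tolerance of 0.02. The factors ran from 0.5188 to 1.1071. The software of the counting and scaling step is not given in the sources used here either. The deposited data hold 2 tables. One gives 750 endogenous genes, 20 reference genes, 6 positive control probes and 8 negative control probes, per the file headers. The other gave identical values for the 770 genes and lacks the control probes.

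The recovered counts gave the depth. They totalled 1324888, 1364415 and 1350434 in replicates 1 to 3 labelled PD-L1, and 1515104, 1051274 and 1920476 in replicates 1 to 3 labelled empty plasmid. The positive control probes held 25553 to 41454 counts. The top 5 genes took 26.5 to 38.0% of the endogenous counts. The reference genes' mean log2 value still ran from 9.768 to 10.29 between samples after the authors' scaling. The deposited accessions of 746 genes were matched to RefSeq's gene table for the assembly GRCm38.p6, which was used for names only. For 9 genes the current symbol differs from the deposited one, which is kept here (the macrophage gene Emr1 is now Adgre1). No genome build is named, so no coordinates are given.

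Genes were tested when their mean over the 6 samples was at or above the mean of the negative controls plus 2 SD on the log2 scale, a background limit of 4.66 (25.3 on the linear scale). This kept 541 of 750 genes and left out 209. The groups were compared on the values as deposited with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a mean-variance trend, the group as the only term and Benjamini-Hochberg adjustment at 0.05. Differences are the group labelled PD-L1 minus the group labelled empty plasmid. For single values two-sided exact permutation tests were run. The design chosen before the data were examined named a count-based test for raw counts and limma for log2 values, so limma was used. The alternative tests meant for deposited raw counts were not run, because the deposited values are log2, but limma's voom was run on the recovered counts.

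The 25 gene lists were fixed before the data were examined, as were most of the other settings tried and the rule for named genes. The 20 lists with 5 or more tested genes were tested with limma's camera with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Cd274 was left out of every list. The naming rule took Cd274 and Pdcd1, then the genes past the threshold with no overlap between groups. As fewer than 10 passed, it took the 10 genes with the smallest p in each direction, the 4 members with the smallest p of each of the 4 lists with the smallest camera p, and 2 members of each other tested list. It gave 59 genes, not all of which are described here, and other genes named are marked as chosen later.

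The tests were tested on simulated data for this comparison, with 541 genes of which 150 were changed, in 20 runs. limma called 37.3% of genes changed by 1 on the log2 scale, 77.2% of those changed by 2 and 94.6% of those changed by 4, and 4.35% of its calls were false. A shifted list was called in 20 of 20 runs, and 0 runs without change had a list called. Genes varied independently in this simulation, unlike the real lists. Alternatives covered the scaling between samples, the trend, the background limit, the added constant, subtraction of the negative controls, the other table, a replicate block and leaving out each sample. A background limit set on the linear scale, voom scaled by the reference genes, a hepatocyte covariate and 2 shortened lists were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.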

Results

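Immune gene expression was measured in tumors that grew from a mouse liver cancer cell line in the liver of male BALB/c mice aged 6 to 7 weeks. The line, BNL-MEA, had been transfected either with a plasmid for PD-L1, the ligand of the inhibitory T cell receptor PD-1, or with the empty plasmid, and stable clones were injected under the capsule of the left liver lobe. Total RNA of tumor tissue was hybridized to a NanoString nCounter panel, which counts single RNA molecules by barcoded probes. Each plasmid was carried by its own clones, so a difference between clones cannot be told apart from an effect of PD-L1. The labels put 3 samples in the PD-L1 group and 3 in the empty plasmid group. They do not say whether the 3 samples of a group came from separate mice. The p-values therefore measure only the spread between these samples, which may not be a spread between mice. The protocol text of the empty plasmid samples also speaks of PD-L1-expressing clones, so the grouping rests on the sample titles. The panel read 750 immune-related genes and 20 reference genes. Between 1051274 and 1920476 counts per sample could be recovered from the deposited values, against 72 to 109 counts over the 8 negative control probes. Replicates of a group correlated across genes with r between 0.908 and 0.954, and genes are not independent replicates. No 2 replicates agreed within counting noise, with a chi-square per degree of freedom of at least 145.4.

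The comparison of the groups asked how the immune transcripts of tumors from PD-L1-transfected cells differed from those of empty plasmid tumors. Cd274, the mouse gene for PD-L1, was not higher in the samples labelled PD-L1. Its log2 values were 6.17, 5.36 and 5.87 in replicates 1 to 3 labelled PD-L1, and 6.95, 5.32 and 7.43 in replicates 1 to 3 labelled empty plasmid. The group means were 5.80 ± 0.41 and 6.56 ± 1.10 (SD, n = 3 each), a difference of -0.76 ± 0.59 (SE) with a 95% interval from -2.18 to 0.65 (adjusted p = 0.557, limma). A two-sided exact permutation test gave p = 0.4, where 3 against 3 samples cannot give a p under 0.1. Without empty plasmid replicate 2 the difference was -1.39, and without empty plasmid replicate 3 it was -0.33. Where the Cd274 probe lies on the transcript, and whether the plasmid's transcript holds that part, is not in the sources used here, so the probe checks the labels in neither direction. For that reason the groups are called labelled PD-L1 and labelled empty plasmid throughout. Pdcd1, the gene for PD-1, stood at 4.69 ± 0.87 in the samples labelled PD-L1 and 5.39 ± 1.23 in the others (SD, n = 3 each; exact permutation p = 0.5).

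The 10 genes with the smallest p among those higher in the samples labelled PD-L1 were F13a1, Mrc1, Clec4n, Ccl6, Ccr1, C5ar1, Fpr2, Lgals3, Cd80 and Msln. F13a1, the A subunit of coagulation factor XIII, which macrophages make, was higher by 4.19 ± 0.60 on the log2 scale (SE, n = 3 per group). Mrc1, the macrophage mannose receptor, was higher by 2.53 ± 0.53, and Clec4n, the fungal-sugar receptor dectin-2 of myeloid cells, by 2.26 ± 0.36. The chemokine Ccl6 was higher by 3.14 ± 0.63 and the chemokine receptor Ccr1 by 1.69 ± 0.39. C5ar1, the receptor of the complement fragment C5a, was higher by 0.87 ± 0.21 and the formyl peptide receptor gene Fpr2 by 1.37 ± 0.34. Lgals3, for galectin-3, was among the most abundant transcripts and was higher by 1.22 ± 0.31. Cd80, a ligand of CD28 and CTLA-4, was higher by 1.60 ± 0.36. Msln, for mesothelin, a surface protein of mesothelial cells and some tumors, was higher by 3.02 ± 0.48. For each of these 10 genes all 3 samples labelled PD-L1 stood above all 3 samples labelled empty plasmid.

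Among the genes lower in the samples labelled PD-L1, the 10 with the smallest p were the following. Ccl5, a chemokine that attracts T cells, differed by -1.78 ± 0.51 (log2, SE, n = 3 per group). Cyfip2, which takes part in actin remodelling, differed by -1.82 ± 0.36 and the nuclear receptor gene Rora by -2.21 ± 0.61. The interferon-induced gene Oas2 differed by -1.29 ± 0.35, and Tnfsf13b, the B cell survival factor BAFF, by -1.30 ± 0.37. Il6st, the shared signalling receptor of the IL-6 family, differed by -0.77 ± 0.22, the kinase gene Map3k5 by -1.12 ± 0.29 and the transcription factor gene Jun by -0.80 ± 0.22. Selplg, the selectin ligand PSGL-1, differed by -0.81 ± 0.24. Il17rb, a subunit of the IL-25 receptor, differed by -2.21 ± 0.65, but its mean of 3.56 in the samples labelled PD-L1 lay under the background limit of 4.66. Its difference was -4.18 with the negative controls subtracted. With the hepatocyte list's mean as a covariate, a setting added after the values were seen, Il17rb differed by -0.81 and Rora by -0.96. For each of these 10 genes all 3 samples labelled PD-L1 stood below all 3 others.

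None of these genes passed the test. In limma, 0 of 541 tested genes had an adjusted p under 0.05, and the lowest adjusted p was 0.103, shared by F13a1, Msln and Clec4n. At an unadjusted p under 0.05 there were 92 genes, 39 higher and 53 lower, which is 17% where chance gives 5%. The groups did not overlap for 99 genes, 18.3% where chance gives 10%. When the values were rescaled to the reference genes, 1 gene passed, F13a1, with an adjusted p of 0.0448 over a range of 0.0448 to 0.57 across its alternatives. The count of 92 became 38 without labelled PD-L1 replicate 2 and 53 without labelled empty plasmid replicate 3. The median difference over all tested genes was -0.12, and the sample medians of the groups differed by -0.16.

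**Figure D1:**
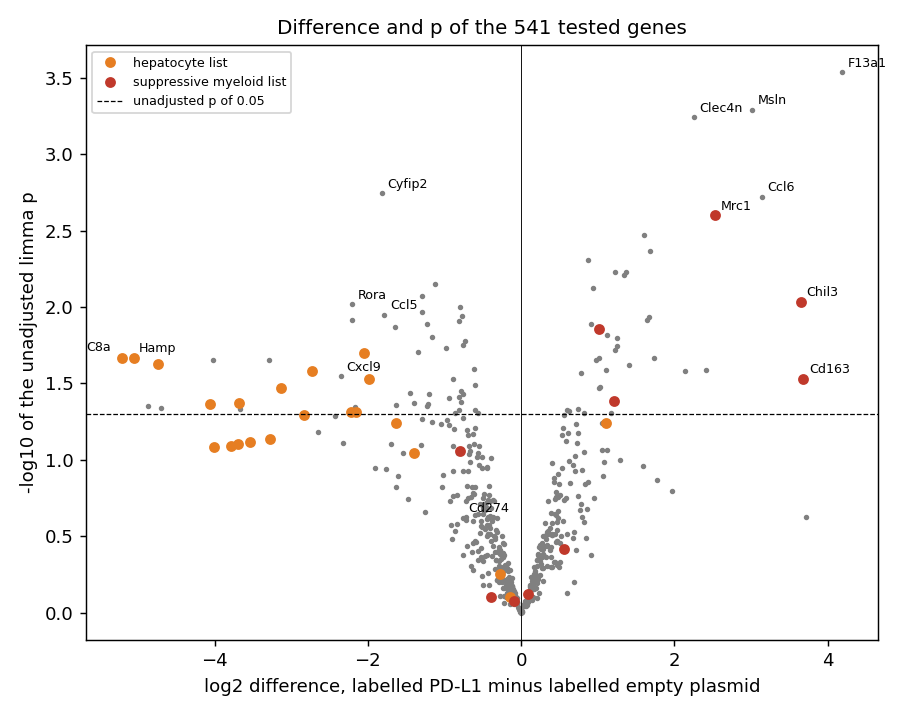
Log2 difference (labelled PD-L1 minus labelled empty plasmid, x axis) against -log10 of the unadjusted limma p (y axis) for the 541 tested genes, one point each, with the hepatocyte and suppressive myeloid lists in color. The dashed line marks an unadjusted p of 0.05, and F13a1, Msln and Clec4n, at the top right, had an adjusted p of 0.103.

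Genes of hepatocytes and liver-made plasma proteins differed most between the groups. Of 22 tested members 21 were lower in the samples labelled PD-L1, with a median log2 difference of -2.98. C8a, a subunit of complement C8, differed by -5.21 ± 1.74 (SE, n = 3 per group) and Hamp, for the iron hormone hepcidin, by -5.05 ± 1.68. Ambp, for a plasma protein precursor, differed by -4.74 ± 1.62 and Serping1, the C1 inhibitor, by -2.05 ± 0.67. The list's mean was 7.81 ± 1.69 in the samples labelled PD-L1 and 10.56 ± 1.72 in the others (SD, n = 3 each). The samples overlapped: labelled PD-L1 replicates 1 to 3 stood at 7.10, 6.59 and 9.74, and labelled empty plasmid replicates 1 to 3 at 8.74, 12.17 and 10.76. The exact permutation p of this mean was 0.2. limma's camera test with a preset correlation called the list lower (adjusted p = 1.56e-05), but its members varied together within groups, and the adjusted p was 0.778 with an estimated correlation. Of its members 0 passed, either over all genes or adjusted over the list alone, and 11 had an unadjusted p under 0.05. No member belonged to another list.

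Genes of alternatively activated or suppressive myeloid cells were higher as a group in the samples labelled PD-L1. Of 10 tested members 7 were higher, with a median log2 difference of 0.79 and a mean of 1.14. Besides Mrc1, the chitinase-like gene Chil3 was higher by 3.65, with a 95% interval from 1.25 to 6.05. The hemoglobin scavenger receptor gene Cd163 was higher by 3.68 ± 1.33 (SE, n = 3 per group). Il4ra, the IL-4 receptor chain through which this activation is induced, was higher by 1.01 ± 0.30. Chil3 stood at 4.31 in the samples labelled empty plasmid, under the background limit. Mrc1, Chil3 and Cd163 had the largest rises of the list, which put its mean above its median. Mrc1 and Cd163 belong to the macrophage list too, and this list was not tested without its leading members. Arg1, a list member that hepatocytes also express at high levels and that was named after its value was seen, differed by -0.40 ± 1.43. Single samples set its direction: it stood at 11.1, 10.4 and 11.1 in replicates 1 to 3 labelled PD-L1. In replicates 1 to 3 labelled empty plasmid it stood at 7.7, 13.4 and 12.6. The list's mean was 9.40 ± 0.48 against 8.26 ± 0.54 (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). Adjusted over the list alone 3 members passed, and 0 passed over all genes. The camera call (adjusted p = 0.0209) was lost with an estimated correlation (adjusted p = 0.646), and also without labelled PD-L1 replicate 1 (adjusted p = 0.116) or labelled empty plasmid replicate 1 (adjusted p = 0.142). With the hepatocyte list's mean as a covariate, added later, the mean was 1.07 (camera adjusted p = 0.0153).

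Among genes of macrophages and monocytes, 13 of 18 tested members were higher in the samples labelled PD-L1, with a median log2 difference of 0.36 and a mean of 0.55. The 3 members with the smallest p were Mrc1, Cd163 and Msr1, all scavenger or lectin receptors, of which Msr1 was higher by 1.02 ± 0.38. C1qa, a complement component that tissue macrophages make, was higher by 0.48 ± 0.32. Adjusted over the list alone 1 member passed, and 0 over all genes. The list's mean was 10.39 ± 0.37 against 9.84 ± 0.26 (SD, n = 3 each; exact permutation p = 0.2). Camera called it (adjusted p = 0.0209), and also with the hepatocyte list's mean as a covariate, added later (mean 0.49, adjusted p = 0.0171). It did not call the list with an estimated correlation (adjusted p = 0.778). Without Mrc1, Cd163 and Msr1, a choice made after the values were seen, the mean difference was 0.18 (adjusted p = 0.167). The call also ended without labelled PD-L1 replicate 2 (adjusted p = 0.0612), labelled PD-L1 replicate 3 (adjusted p = 0.146) or labelled empty plasmid replicate 2 (adjusted p = 0.0766). The group with the higher mean of both myeloid lists had the lower mean of the hepatocyte list, 7.81 against 10.56, though single samples of the macrophage list overlapped.

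Genes of antigen presentation by MHC class I were lower as a group in the samples labelled PD-L1, where the hepatocyte list was lower too. Of 16 tested members 14 were lower, with a median log2 difference of -0.54 and a mean of -0.81. The classical class I gene H2-K1 differed by -0.98 ± 0.32 and the non-classical H2-T23 by -0.81 ± 0.32 (SE, n = 3 per group). H2-Q10, a class I gene that the liver secretes, differed by -4.70 ± 1.91, while H2-M3 was higher by 0.59 ± 0.28. With the hepatocyte list's mean as a covariate H2-Q10 differed by -0.17 and H2-M3 by 0.25. In that setting H2-K1 differed by -1.20 and H2-T23 by -0.64. The list's mean was 8.62 ± 0.31 against 9.43 ± 0.19 (SD, n = 3 each; exact permutation p = 0.1), and 0 members passed, over all genes or adjusted over the list alone. Camera called the list (adjusted p = 0.0395), but not with an estimated correlation (adjusted p = 0.646). Without H2-Q10, Cd1d1 and Cd1d2, chosen after the values were seen, the mean difference was -0.39 (adjusted p = 0.115). With the hepatocyte list's mean as a covariate, also added later, it was -0.43 (adjusted p = 0.087). The call ended as well without labelled PD-L1 replicate 3 (adjusted p = 0.0901), labelled empty plasmid replicate 1 (adjusted p = 0.115) or labelled empty plasmid replicate 2 (adjusted p = 0.0766).

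Genes of IL-6, JAK and STAT signalling were also lower as a group, beside the lower hepatocyte list of the same samples. Of 15 tested members 13 were lower, with a median log2 difference of -0.40 and a mean of -0.41. Besides Il6st, the interferon-signalling factor gene Stat2 differed by -0.76 ± 0.24 (SE, n = 3 per group). The list's mean was 8.05 ± 0.17 against 8.46 ± 0.19 (SD, n = 3 each; exact permutation p = 0.1), and 0 members passed, over all genes or adjusted over the list alone. Camera called it (adjusted p = 0.0417), and also with the hepatocyte list's mean as a covariate, added later (mean -0.57, adjusted p = 0.0153). It did not call the list with an estimated correlation (adjusted p = 0.778). The call ended when samples were centred on their medians (mean -0.25, adjusted p = 0.0714), and without labelled PD-L1 replicate 2 (adjusted p = 0.0612), labelled PD-L1 replicate 3 (adjusted p = 0.198), labelled empty plasmid replicate 1 (adjusted p = 0.142) or labelled empty plasmid replicate 3 (adjusted p = 0.104).

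**Figure D2:**
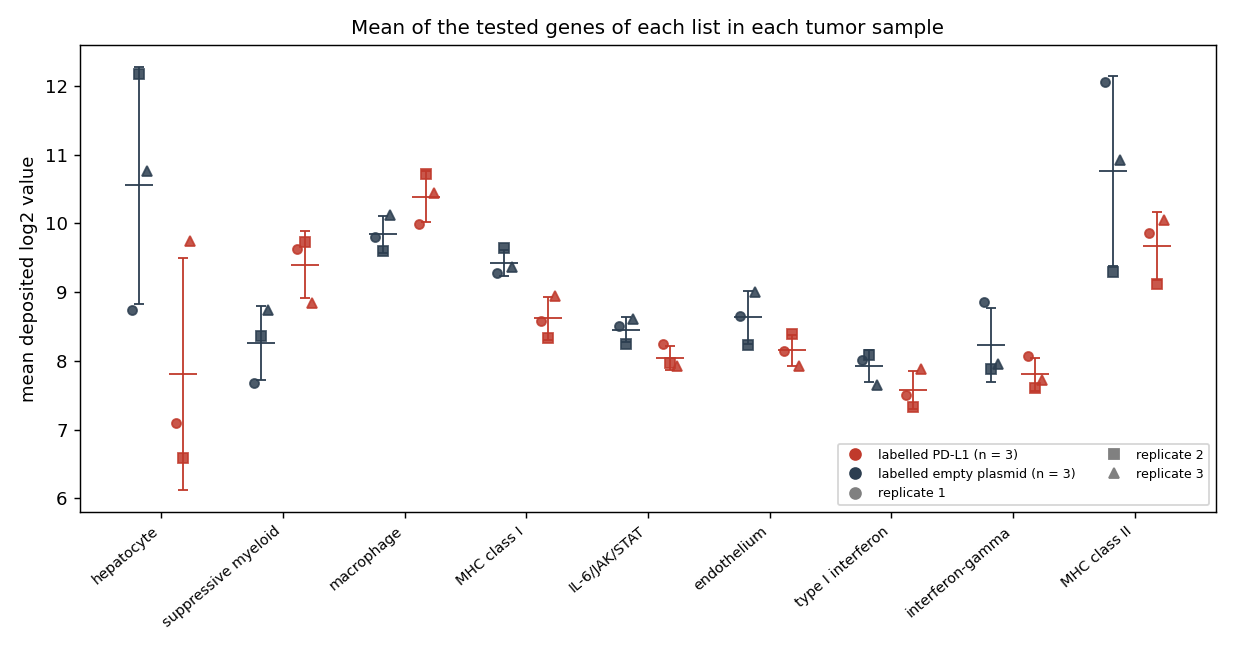
Mean deposited log2 value (y axis) of the tested genes of 9 lists (x axis) in each of the 6 samples, with the group mean as a horizontal line and bars of ± 1 SD (n = 3). In the suppressive myeloid, MHC class I and IL-6, JAK and STAT lists the groups do not overlap. The IL-6, JAK and STAT groups nearly touch, at 8.2455 in labelled PD-L1 replicate 1 and 8.2481 in labelled empty plasmid replicate 2. The hepatocyte list runs from 6.59 to 9.74 in the samples labelled PD-L1 and from 8.74 to 12.17 in the others.

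In the interferon, MHC class II and endothelial lists most members were lower in the samples labelled PD-L1, and none of these 4 lists passed in the main test. The hepatocyte list was lower in the same group, 7.81 against 10.56. Of 25 tested type I interferon response genes 19 were lower (median log2 difference -0.44; camera adjusted p = 0.148), with the RNA sensor gene Ddx58 at -0.73 ± 0.23 (SE, n = 3 per group). Of 18 interferon-gamma response genes 15 were lower (median -0.42; adjusted p = 0.167). Cxcl9, a T cell attractant induced by interferon-gamma, differed by -2.35 ± 0.84. Of 8 MHC class II presentation genes 7 were lower (median -1.54; adjusted p = 0.193). Their spread within the group labelled empty plasmid was wide, with 14.10, 10.19 and 12.76 for H2-Aa in replicates 1 to 3. H2-Aa differed by -1.77 ± 0.97 and the invariant chain gene Cd74 by -1.90 ± 1.04. Of 11 endothelial genes 10 were lower (median -0.51; adjusted p = 0.0864), with Icam2 at -0.81 ± 0.33 and Tie1 at -0.87 ± 0.39. In each of these 4 lists 0 members passed, over all genes or adjusted over the list alone. Single samples weighed on these lists in both directions. The mean of the MHC class II list, -1.09, was -1.82 without labelled empty plasmid replicate 2 (adjusted p = 0.014) and -0.44 without labelled empty plasmid replicate 1 (adjusted p = 0.757). That of the interferon-gamma list, -0.43, was -0.57 without labelled empty plasmid replicate 3 (adjusted p = 0.025) and -0.12 without labelled empty plasmid replicate 1 (adjusted p = 0.896). That of the type I interferon list, -0.35, was -0.48 without labelled empty plasmid replicate 3 (adjusted p = 0.0139) and -0.23 without labelled PD-L1 replicate 2 (adjusted p = 0.34). That of the endothelial list, -0.48, was -0.68 without labelled empty plasmid replicate 2 (adjusted p = 0.02), -0.59 without labelled PD-L1 replicate 2 (adjusted p = 0.0166) and -0.29 without labelled empty plasmid replicate 3 (adjusted p = 0.244). With the hepatocyte covariate the means were -1.89 for MHC class II (adjusted p = 0.0147), -0.87 for interferon-gamma (adjusted p = 0.0088), -0.79 for endothelial (adjusted p = 0.0147) and -0.12 for type I interferon genes (adjusted p = 0.999). Each adjusted p given here used the preset correlation of 0.01. The estimated correlation was 0.66 for MHC class II, 0.27 for interferon-gamma, 0.28 for endothelial and 0.16 for type I interferon genes. With it the adjusted p in the main fit was 0.778 for each of these 4 lists. The fits without a sample or with the covariate were not repeated with an estimated correlation. Other settings under which these lists passed are given with the alternatives.

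In the remaining lists members went both ways. Of 23 chemokine genes 11 were higher. The list's median was -0.11 while its mean was 0.34 and the test's direction up (camera adjusted p = 0.167), and 1 member, Ccl6, passed when adjusted over the list alone. The list's mean was 0.62 without labelled empty plasmid replicate 1 (adjusted p = 0.0394) and 0.13 without labelled empty plasmid replicate 2 (adjusted p = 0.41), and it turned to -0.06 with the hepatocyte covariate. The background limit left out 15 of 23 natural killer cell genes, and with no limit the list's mean was 0.19. Of the 8 tested genes 6 were lower (median -0.63, camera adjusted p = 0.277). Their mean, -0.65, was -1.18 without labelled empty plasmid replicate 2 (adjusted p = 0.0328), -0.996 without labelled PD-L1 replicate 3 (adjusted p = 0.146), -0.32 without labelled PD-L1 replicate 2 (adjusted p = 0.648) and -0.23 without labelled empty plasmid replicate 1 (adjusted p = 0.778). The activating receptor gene Klrk1 differed by -1.20 ± 0.46 and the chemokine gene Xcl1 by -1.69 ± 0.82 (SE, n = 3 per group), both with means under the background limit in the samples labelled PD-L1. Across the alternatives Klrk1 ran from -2.37 to -0.89 and Xcl1 from -2.87 to -0.80. Of 6 dendritic cell genes 3 were higher (median 0.39, mean 0.06; adjusted p = 0.283). The mean was -0.28 without labelled PD-L1 replicate 3, 0.28 without labelled PD-L1 replicate 1 and 0.56 with the hepatocyte covariate. Clec4n passed when adjusted over the list alone. Hsd11b1, a member that hepatocytes also express, differed by -2.65 ± 1.20. Of 11 granulocytic genes 5 were higher (adjusted p = 0.418), with the calprotectin gene S100a8 higher by 1.67 ± 0.48. Their median of -0.004 and mean of -0.10 were below 0 while the test's direction was up. Without each sample in turn that mean ran from -0.42 (without labelled PD-L1 replicate 3) to 0.07 (without labelled PD-L1 replicate 2). Of 11 early complement and complement receptor genes 7 were higher (median 0.28, mean 0.07; adjusted p = 0.237), among them the properdin gene Cfp by 1.03 ± 0.38. The mean was -0.08 without labelled empty plasmid replicate 1 and 0.31 with the hepatocyte covariate. Of 7 checkpoint and costimulatory ligand genes 4 were higher (median 0.004; adjusted p = 0.671). Cd80 passed when adjusted over that list alone, and Icosl differed by -0.43 ± 0.33. In the natural killer, granulocytic and complement lists 0 members passed when adjusted over the list alone.

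Fibroblast and matrix genes (7 of 12 higher, median log2 difference 0.20, camera adjusted p = 0.277) included the abundant Vim, higher by 0.47 ± 0.38, and Itgb1, higher by 0.40 ± 0.21 (SE, n = 3 per group). Vim was higher by 0.19 without labelled PD-L1 replicate 1 and by 0.69 without labelled PD-L1 replicate 3. Toll-like receptor and NF-kappaB genes were higher in 16 of 33 cases (median -0.02, mean -0.01, test direction up, adjusted p = 0.671). Among them Tlr7, an RNA-sensing receptor gene, was higher by 1.18 ± 0.49 and the adaptor gene Traf3 differed by -1.23 ± 0.36. Inflammatory cytokine genes were higher in 5 of 8 cases (median 0.03, mean -0.04, test direction up, adjusted p = 0.671), with Il15 higher by 0.53 ± 0.29. B cell and plasma cell genes were lower in 3 of 5 cases (median -0.27, camera adjusted p = 0.719), with the B cell adaptor gene Blnk at -1.16 ± 0.36. The background limit left out 11 of 16 genes of this list, and with no limit its mean was 0.47. Proliferation and survival genes were lower in 6 of 7 cases (median -0.07; adjusted p = 0.971). In these 5 lists 0 members passed when adjusted over the list alone. The means of the granulocytic, Toll-like receptor, inflammatory cytokine and proliferation lists lay near 0 and changed sign when samples were centred on their medians. Of the 20 lists tested, 5 were called with the preset correlation and 0 with an estimated correlation. fry, which tests whether a list's genes move one way on balance, called 0, and its test for change in either direction called 8.

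Lymphocyte transcripts were mostly too low to test. The background limit left out 10 of 14 T cell genes, 10 of 12 CD8 and cytotoxic genes, 9 of 11 regulatory T cell genes, 6 of 9 inhibitory checkpoint receptor genes and 5 of 9 mast cell, basophil and eosinophil genes, so these 5 lists had fewer than 5 tested genes and no list test. The 4 tested T cell genes were all lower in the samples labelled PD-L1 (mean log2 difference -0.97), including the T cell receptor chain gene Cd3d at -1.05 ± 0.46 and the T cell kinase gene Lck at -0.95 ± 0.42 (SE, n = 3 per group), which were named after their values were seen. The mean of these 4 genes was 4.47, 4.83 and 5.34 in replicates 1 to 3 labelled PD-L1. It was 6.57, 5.29 and 5.69 in replicates 1 to 3 labelled empty plasmid (exact permutation p = 0.2). The mean difference was 0.35 over the 2 tested CD8 and cytotoxic genes, 0.74 over the 2 regulatory T cell genes, -0.27 over the 3 checkpoint receptor genes and 0.78 over the 4 mast cell, basophil and eosinophil genes. Single samples weighed on 2 of these. The CD8 and cytotoxic mean was 5.19, 5.85 and 7.14 in replicates 1 to 3 labelled PD-L1, and 5.91, 5.47 and 5.74 in those labelled empty plasmid. Only labelled PD-L1 replicate 3 stood above all samples labelled empty plasmid. The checkpoint receptor mean was 4.95, 4.44 and 5.23 against 5.22, 4.88 and 5.33 in the same order. Adjusted over the list alone, 1 regulatory T cell gene passed, Tnfrsf9, which activated T cells and other cells also express and which was higher by 1.02 ± 0.34. It was named after its value was seen, and in the other 4 of these lists 0 members passed.

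**Figure D3:**
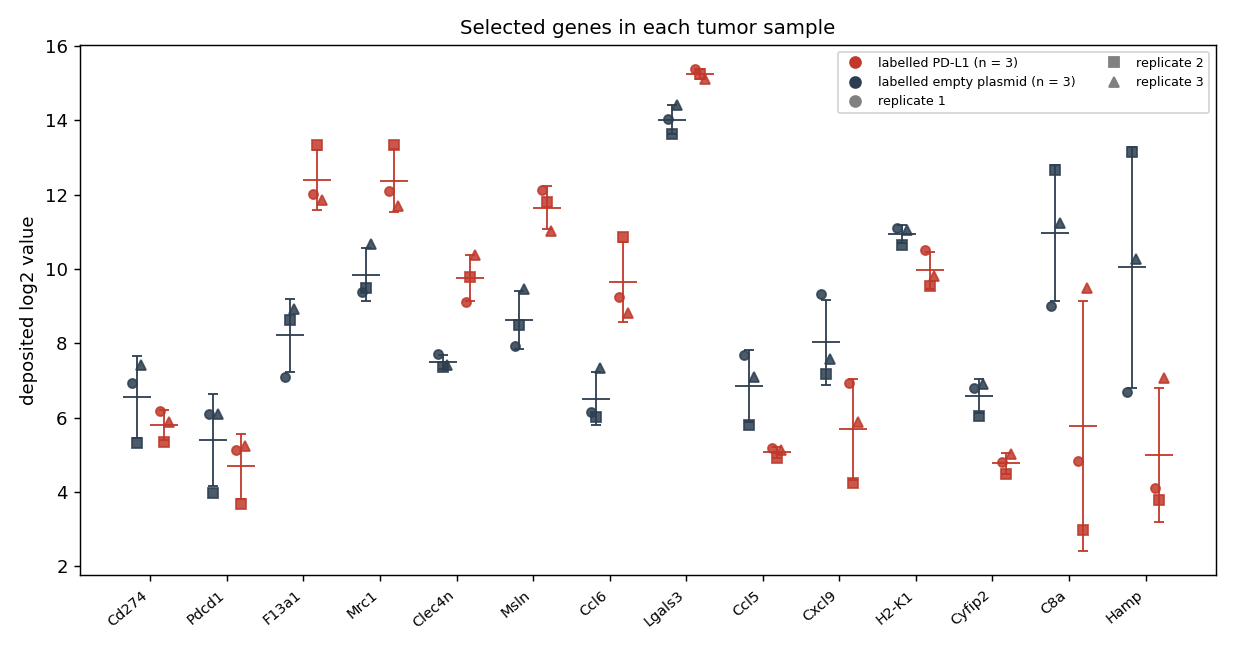
Deposited log2 value (y axis) of 14 genes (x axis) in each sample, with group means as horizontal lines and bars of ± 1 SD (n = 3), and the replicate number shown by the marker's shape. Cd274 overlaps between the groups, F13a1 and Mrc1 do not, and C8a and Hamp spread widely within both groups.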

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

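The estimated correlation was among the settings planned before the values were seen; the other tests in this part were chosen after. Among the 209 genes left out for their low mean, 3 stood out because their mean in the samples labelled PD-L1 lay above the background limit and all 3 of these samples exceeded all 3 samples labelled empty plasmid. The log2 difference was 1.62 for Ifna1, a type I interferon gene, 1.84 for Tnfsf18, the ligand of the costimulatory receptor GITR, and 1.07 for the neutrophil-attracting chemokine gene Cxcl2. Their means in the samples labelled empty plasmid, 3.27, 3.11 and 3.69, lay under the background limit, so the sizes are uncertain. Without overlap between the groups, 26 of the left-out genes were higher and 16 lower, 20.1% where chance gives 10%. Among the 20 reference genes, used in no comparison of genes, Polr1b was higher in all 3 samples labelled PD-L1, by 0.42. In the opposite direction, 5 left-out genes had a mean above the limit in the samples labelled empty plasmid and all 3 samples labelled PD-L1 below them. Their log2 differences were -2.05 for the natural killer receptor family gene Klra17, -1.13 for the T cell costimulator gene Icos, -1.18 for Il1a, -0.98 for the adenosine receptor gene Adora2a and -0.84 for the chemokine receptor gene Cxcr3.

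Hepatocyte genes were lower in the samples labelled PD-L1, with a median log2 difference of -2.98. The tables argue against the authors' scaling as the whole of it: on the recovered counts, with the authors' factor removed, the list's mean difference was -2.97, and the mean log2 factor differed between the groups by 0.21. A differing share of surrounding liver in the samples is a candidate explanation: the 22 genes varied together within groups, with an estimated correlation of 0.79 where genes that vary singly would give a value near 0. Apoe, the list's most abundant member, which macrophages also express, differed by -0.27 ± 0.44 (SE, n = 3 per group). Liver differentiation of the tumor cells themselves, which come from a liver line, would also move these genes together and stays open. An effect of PD-L1 was not tested and stays open too, as does a difference between the clones. Chance was not settled either, since 3 against 3 samples make only 10 splits: the real split gave a mean difference of 2.75 in size, the highest other split 3.42, and 2 splits reached the real value.

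Suppressive myeloid genes were higher in the samples labelled PD-L1 by 1.14 in the mean and 0.79 in the median, with the largest rises in Mrc1, Chil3 and Cd163. Whether a lower liver share alone raised them stays open. The list moved apart from the endothelial list by 1.62 ± 0.37 (SE, n = 3 per group, exact permutation p = 0.1, the smallest possible). The endothelial list itself differed by a mean of -0.48. This contrast cannot decide, because surrounding liver holds endothelial cells too, whose genes would fall with the liver share. Macrophages of the surrounding liver may also have added to the list's values, though their genes would fall with the liver share. The group with the higher list mean had the lower hepatocyte mean, 7.81 against 10.56. The list's mean went against the hepatocyte mean over the 6 samples, but not clearly, with Pearson's r = -0.60 (exact permutation p = 0.2, adjusted p = 0.332) and Spearman's rho = -0.66 (exact permutation p = 0.175, adjusted p = 0.35). Without the 2 samples farthest from the median r was -0.35, and 4 such relations were computed. These relations pool the 2 groups, whose means of both lists already differed in opposite directions, so they cannot decide. In replicates 1 to 3 labelled PD-L1 the list's mean was 9.62, 9.74 and 8.85, lowest where the hepatocyte mean was highest (9.74). In replicates 1 to 3 labelled empty plasmid it was 7.68, 8.37 and 8.74, lowest where the hepatocyte mean was lowest (8.74). A difference between tumors of the 2 plasmids stays open as the biological explanation. Within it, an effect of PD-L1 cannot be told apart from a difference between the clones. Of the 10 genes 3 belong to other lists too.

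Cd274 was not higher in the samples labelled PD-L1. Endogenous Cd274 that follows interferon-gamma could hide a plasmid effect, which stays open. Over the 6 samples Cd274 and the mean of the interferon-gamma list had Pearson's r = 0.59 (exact permutation p = 0.212, adjusted p = 0.332). Spearman's rho was 0.66 (exact permutation p = 0.175, adjusted p = 0.35), and r was 0.36 without the 2 farthest samples. These values pool the groups, whose means of both were lower in the samples labelled PD-L1, so they cannot decide. A probe outside the plasmid's transcript would also leave the value unmoved, and this cannot be told apart from a plasmid effect within the 95% interval, whose upper end is 0.65, because the probe's position is not in the sources used here. Loss of plasmid expression in the animal was not tested.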

How the results depend on the processing

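The covariate, the linear-scale limit, voom and the shortened lists were chosen after seeing the data; the other alternatives were planned. The 2 planned count-based tests with size factors were not run, because the values are log2. The count of 0 genes held in 19 of 20 alternatives, and became 1 (F13a1) with rescaling to the reference genes, where the cause was not tested. It was 0 without each sample in turn. Genes at an unadjusted p under 0.05 ranged from 32 (hepatocyte covariate) to 119 (no limit on low values). Cd274 kept its direction and side of the threshold in all 20 alternatives, from -1.39 to -0.33. Replicate numbers did not pair the samples, with correlations of 0.27, -0.20 and -0.13 between same-numbered samples, so not every sample correlated best with its own number. The samples numbered 1 were each other's best match, but the strongest match, at 0.46, was replicate 3 labelled PD-L1 with replicate 2 labelled empty plasmid. With the replicate block 0 genes and 5 lists passed and 80 genes had an unadjusted p under 0.05; the IL-6 list missed at -0.41.

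The number of lists called, 5, became 3 with rescaling to the reference genes, 3 at double the limit, 3 with voom, 0 with an estimated correlation and 0 with fry, and 2 to 6 without each sample in turn. It was 7 with no limit on low values and 6 with the hepatocyte covariate, and 4 or 5 in the other settings. The cause of these changes was not tested. An estimated correlation and fry leave the list means as they are, at -2.75 for hepatocyte, 1.14 for suppressive myeloid, 0.55 for macrophage, -0.81 for MHC class I and -0.41 for IL-6 genes. MHC class I also missed at -0.78 (reference genes), -0.83 (double limit), -0.79 (voom), -0.43 (covariate) and -0.39 (without H2-Q10, Cd1d1 and Cd1d2), macrophages at 0.18 (without Mrc1, Cd163 and Msr1). IL-6 missed at -0.25 (centred on medians), -0.38 (reference genes), -0.41 (double limit), -0.34 (linear limit) and -0.39 (voom).

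Without each sample in turn, the mean log2 difference ran from 0.38 to 0.75 for macrophage, 0.85 to 1.42 for suppressive myeloid, -0.97 to -0.66 for MHC class I and -0.51 to -0.33 for IL-6 genes. That of the hepatocyte list ran from -3.72 to -1.94, without labelled PD-L1 replicate 3 and without labelled empty plasmid replicate 2. Other results turned, and the cause was not tested. For genes the sign of the difference turned: Hsd11b1 to 0.21 with the hepatocyte covariate, Ccnd3 to 0.0059 and Bcl2l1 to 0.0249 with quantile normalization, where Vim was at 0, and Bcl2l1 to 0.0243 with centring on medians. Without each sample in turn, Ccnd3 ran from -0.49 to 0.10 and Bcl2l1 from -0.38 to 0.15. For lists the direction of the test turned, which compares a list with the other genes and can differ from the sign of its mean. This was so, with the mean given, for the Toll-like receptor list at -0.18 and the fibroblast list at -0.25 with the hepatocyte covariate, the Toll-like receptor list at -0.0085 with fry, and the natural killer list at 0.19 and the B cell list at 0.47 with no limit on low values. It was so for the proliferation list at 0.0538 with quantile normalization, 0.0779 with centring on medians, 0.0718 with the linear limit, -0.0777 with the replicate block and -0.0498 with voom. It was also so without some samples, where the means ran from -0.47 to -0.0259 for B cell, -0.22 to 0.0807 for inflammatory cytokine, -0.0735 to 0.0914 for Toll-like receptor, -0.17 to 0.33 for fibroblast and -0.21 to 0.0741 for proliferation genes. Among named genes 1141 gene and setting pairs kept direction and side, 7 changed sign, 1 was at 0 and 1 passed the threshold. Sizes moved more: with the hepatocyte covariate, 8 of 54 named genes had a difference smaller than the main one by a factor over 1.5, or turned, and 7 a larger one by that factor, which was chosen after seeing the values. The 15 lists not called kept direction and side in 300 list and setting pairs, passed the threshold in 13 and turned in the test's direction in 17. The sign of the mean itself changed in 38 of these 330 pairs, in 11 of the 15 lists. Those that passed with all 6 samples were the type I interferon (adjusted p = 0.0397) and endothelial lists (adjusted p = 0.0396) with no limit on low values, the MHC class II list with the replicate block (adjusted p = 0.026), and the MHC class II (adjusted p = 0.0147), interferon-gamma (adjusted p = 0.0088) and endothelial lists (adjusted p = 0.0147) with the hepatocyte covariate. All of these calls used the preset correlation, and with an estimated correlation 0 lists were called. Signal over background limits what can be said of the 209 genes under the limit set by the negative controls, which the main test left out and only settings with a lower limit or none included.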

Other observations

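All tests in this part were chosen after the values were seen. The genes in this paragraph were picked after their values were seen and stand for no group: the chemokine and granulocytic lists went both ways, and 0 genes passed the adjusted threshold in limma, against 92 at an unadjusted p under 0.05. Lyz2, for lysozyme of macrophages and neutrophils, was higher by 1.41 ± 0.48 on the log2 scale (SE, n = 3 per group), the chemokine gene Ccl9 by 1.64 ± 0.48 and the eosinophil attractant gene Ccl11 by 1.73 ± 0.58. The platelet chemokine gene Ppbp was higher by 1.25 ± 0.40, and Prg2, for a granule protein of eosinophils, by 0.78 ± 0.27, from a mean of 4.46 that lay under the background limit. Lcn2, for the iron-binding protein lipocalin-2, differed by -3.67, with a 95% interval from -7.26 to -0.08.

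Some genes outside the hepatocyte list followed its mean from sample to sample. With the group kept in the limma fit, 6 of 519 genes had an adjusted p under 0.05 for this slope. They were the tryptophan-degrading enzyme gene Tdo2 (1.77 per log2 unit of the list's mean, adjusted p = 0.005), Dpp4 (0.91), the coagulation factor gene F12 (1.18), H2-Q10 (1.65) and Hsd11b1 (1.04), and, in the opposite direction, the monocyte chemokine gene Ccl8 (-1.08), each of the last 5 with an adjusted p of 0.0241. The first principal component held 57.9% of the variance over the tested genes. It placed replicates 1 and 2 labelled PD-L1 at one end (-17.0 and -21.7), replicates 2 and 3 labelled empty plasmid at the other (21.9 and 12.0), and replicate 3 labelled PD-L1 beside replicate 1 labelled empty plasmid (2.36 and 2.44).

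The reference gene Alas1, a heme synthesis enzyme gene with high expression in liver, ran from 7.53 to 10.50 in the samples labelled empty plasmid, the widest range of the 20 reference genes in that group.

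The 6 samples can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 92 genes at an unadjusted p under 0.05, the highest of the others 50, so 1 of 10 splits reached the real count. It gave 0 genes at the adjusted threshold, as did 10 of 10 splits. With the preset correlation it called 5 lists and the highest other split 7, with 4 of the 10 splits calling at least 5.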
